A study of Mus musculus with 3 samples.

How the data were processed

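The series holds 3 droplet single-cell RNA libraries of mouse dorsal skin, 1 per group. Per the labels' protocols, skin was digested in collagenase I, the suspension was passed through a 70 µm strainer, and cells were captured with the 10x Genomics Chromium 3' kit v3.1, which counts molecules by unique molecular identifiers (UMIs) read near the 3' end of each transcript. The young control and the young YAP/TAZ knockout were 2.5 months old and received 0.11 mg tamoxifen per g body weight on 2 days a week for 4 weeks. Both carried floxed Yap1 and Wwtr1 alleles, and the knockout also carried R26-CAG-CreER, a tamoxifen-inducible recombinase driven by a ubiquitous promoter. The old control was 24 months old, wild-type and untreated.

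The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 3.1.0 per the file headers. The genome build mm10 and Seurat 3.1.5 are named per the submitters' processing notes. Barcodes had been selected before deposit, and how this was done is not given in the sources used here. The matrices list 31053 features, of which 71 share a symbol with another feature and were kept apart by their Ensembl identifiers. Gene coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names. They count from 1.

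The libraries held 15290 (young control), 25348 (knockout) and 22108 (old control) barcodes with 95274423, 57767761 and 52579262 UMIs in total. Barcodes with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept, which left 11722, 9408 and 12074. Doublet scores were computed with Scrublet in scanpy 1.11.5. Its automatic threshold marked 3.55% of the barcodes in the young control and 0% in both other libraries, so it had not worked there, and the 8% of barcodes with the highest score were removed from each library instead. This fallback was chosen after the automatic result was seen. The 30691 cells kept were 10824 young control, 8688 knockout and 11179 old control cells.

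Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components, with mitochondrial and ribosomal protein genes, Malat1, Xist and Gm42418 kept out. Cells of all libraries were clustered together without batch correction, on 20 nearest neighbours with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Of the 42 clusters, 25 were named from fixed markers. A cluster stayed unnamed when fewer than 3 markers of its class stood out, when the mean log2 score of the next class lay within 0.5, when more markers of another class than of its own stood among its 10 leading genes, when its UMI count was far below its library's and no own marker led, or when markers of other classes reached 0.5 of their whole-library level. These thresholds were set after the cluster tables were seen. They kept 17 clusters out of every class, with 18.2% of young control, 82.0% of knockout and 59.9% of old control cells. Mixed markers accounted for 8 of these clusters (9.0%, 35.8% and 44.6%) and the missing margin for 6 (3.6%, 43.1% and 4.3%). Leading genes of another class accounted for 2 (5.1%, 3.1% and 8.5%) and too few markers for 1 (0.5%, 0.1% and 2.5%). One of the mixed clusters, number 4, was nearest to fibroblasts and held 2.2%, 0.2% and 10.4% of the cells.

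Counts were summed per library and class and expressed as CPM of that sum. With 1 library per group no test across samples is possible, and no p-value is given. CPM carry exact Poisson 95% intervals, shares carry Clopper-Pearson intervals, and ratios carry exact intervals from the binomial split of both counts. All of them cover counting error only, not differences between animals. Genes were counted by a rule of size: mean CPM of at least 20 over the 3 libraries, a ratio of at least 2 or at most 0.5, and the near bound of its interval past 1.5-fold. Where a library held 0 counts, a bound against a floor of 3 counts in that library's class sum is given. Log2 ratios had 0.5 added to each count.

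For 26 gene lists the median log2 ratio over members with a mean CPM of at least 5 was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is called here when its percentile lies above 97.5 or below 2.5. Percentiles describe these libraries and are not p-values. Lists were also computed in other classes with at least 100 cells in every library, which were keratinocyte-like and vascular endothelial-like cells.

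The grouping, the markers, the gene lists, the size rule and the rule for named genes were fixed before the data were examined. The rule for named genes takes the 12 highest and 12 lowest ratios per comparison, ranked by the near interval bound. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed gene models were left out, as were genes over 10 times more abundant in another class of at least 100 cells in the library with the higher value (taken as free RNA). One gene that this rule takes is not reported here. Yap1 and Wwtr1 are always named. In each list the 2 most abundant members and the 2 with the largest absolute log2 ratio are named too. In other classes the 2 members of a list with the largest absolute log2 ratio and a mean CPM of at least 20 are named. The sex-linked genes counted over whole libraries, 12 circadian clock genes and the values of Acta2 and Isg15 in endothelial-like cells without 1 cluster were chosen after their values were seen.

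The interval, size rule and list percentile were tested on simulated counts for 5955 genes with 3-fold differences planted. For the knockout comparison, 100 of 100 raised and 78 of 100 lowered genes were recovered, 0 of 5755 unchanged genes were called, and 96.0% of intervals held the true ratio. For the old comparison the figures were 100 of 100, 96 of 100, 0 of 5755 and 95.6%. A raised list of 15 genes lay at percentile 100 in both comparisons, and an unchanged list at 60.0 (knockout) and 12.3 (old). The simulated counts were Poisson draws from the young control profile, without variation between cells or libraries. Coverage and the absence of false calls largely follow from that model, and they say nothing about such variation in the real libraries.

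Alternatives set at the outset were a looser filter (200 genes, 500 UMIs, 25% mitochondrial), a stricter one (1000 genes, 2000 UMIs, 10%), doublets kept, each library clustered alone, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors, the mean over cells, cells thinned to 1500 UMIs, free RNA subtracted, genes with at least 10 counts, and list members with a mean CPM of at least 20. Those added after the data were seen were the mixed cluster 4 included, every library weighted to the cluster mix of the young control with and without the thinly filled cluster 13, and the class without cluster 21. Endothelial-like cells without cluster 35, which held cells of 1 library, keratinocyte-like cells without cluster 25, which cell cycle genes led, both classes at 4 to 8% mitochondrial UMIs (for endothelial-like cells also without cluster 35), and the values of single clusters in every class were later choices too. Lists in single clusters are given for at least 15 cells per library. Free RNA was estimated from the level of other classes' markers in the class against the whole library. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.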

Results

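Single-cell transcriptomes were collected from the dorsal skin of a young control mouse group, a young group with tamoxifen-induced deletion of Yap1 and Wwtr1 (the gene of TAZ), and an old wild-type group. YAP and TAZ are transcriptional co-activators held in check by the Hippo pathway. The series title and design place the question in fibroblasts: what loss of YAP/TAZ does at 2.5 months, beside the profile of skin at 24 months. Each group was 1 library, so no difference below has a replicate check, and intervals in brackets are 95% intervals for counting error only. The number of UMIs per deposited barcode differed between libraries. The median barcode held 3568 UMIs in the young control, 1669 in the knockout and 1199 in the old control. The median mitochondrial share was 5.58%, 18.6% and 9.41%, and 12.3%, 62.4% and 19.4% of barcodes exceeded the mitochondrial limit.

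Fibroblast-like cells made up 21.5% [20.7 to 22.3] of young control cells (2328 of 10824), 1.66% [1.40 to 1.95] of knockout cells (144 of 8688) and 2.63% [2.34 to 2.94] of old control cells (294 of 11179). These shares depend on depth, damage and naming, since 82.0% of knockout and 59.9% of old control cells stayed unnamed, and no order of cell abundance is read from them. With a stricter filter they were 25.2%, 4.54% and 6.51%, and with the mixed cluster 4 included the old control share was 13.0%. The class consisted of cluster 6 (led by Col1a1, Col1a2 and Col3a1), cluster 13 (Gpx3, Dpt, C3) and cluster 21 (Coch, Eln, Mfap4). Cluster 6 was the largest of them in the young control (998 cells) and the old control (150), and cluster 21 in the knockout (73), with 55 knockout cells in cluster 6 and 16 in cluster 13. The class sums were 14227072, 978217 and 1922371 UMIs, and the median cell held 5862, 6374 and 6454 UMIs, with a mitochondrial share of 4.49%, 6.88% and 5.03%.

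Of the 2 targeted genes, Wwtr1 was lower in fibroblast-like cells of the knockout library, while the interval of the Yap1 ratio included 1. Wwtr1 (ENSMUSG00000027803, chromosome 3, 57455649 to 57575910, GRCm38) stood at 125 CPM [119 to 131] in the young control, 22.5 [14.1 to 34.1] in the knockout and 114 [99.8 to 131] in the old control. Its knockout ratio was 0.180 [0.112 to 0.273]. With the cluster mix of the young control the ratio was 0.110, and in cells thinned to equal depth it was 0.0366, a level of 1 UMI that cannot be read further. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596) stood at 58.8 CPM [54.9 to 63.0], 49.1 [36.2 to 65.1] and 52.5 [42.8 to 63.8], with a knockout ratio of 0.834 [0.610 to 1.12] and one of 0.558 with the cluster mix of the young control. For old over young control the ratios were 0.914 [0.791 to 1.05] for Wwtr1 and 0.893 [0.719 to 1.10] for Yap1. The labels do not say which exons are floxed, and a 3' tag outside the deleted part checks nothing. Yap1 was lower than in the young control in knockout keratinocyte-like cells (21.3 against 109 CPM). It was not lower in knockout dermal papilla or sheath-like cells (77.3 against 69.5 CPM). Why the classes differ was not tested, so the Yap1 level in fibroblast-like cells neither shows nor excludes deletion.

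Thinned to 1500 UMIs, 16.4% of young control, 0.694% of knockout and 17.1% of old control fibroblast-like cells had a Wwtr1 UMI (47.3%, 11.8% and 49.0% unthinned), after 28, 0 and 1 shallower cells were left out. In T, NK or innate lymphoid-like cells, taken as a background, the thinned shares were 2.46%, 0% (0 of 73 cells, Clopper-Pearson upper bound 4.93%) and 1.42% (5.75%, 1.37% and 4.20% unthinned) at median depths of 2888, 4075 and 4199 UMIs. The thinned knockout share in fibroblast-like cells rests on 1 cell and is not read further. Unthinned, the shares of 11.8% [7.03 to 18.2] and 1.37% [0.0347 to 7.398] had overlapping intervals, and the levels were 22.5 CPM [14.1 to 34.1] in the knockout fibroblast-like and 3.13 CPM [0.0791 to 17.4] in the lymphoid-like cells. For Yap1 the thinned fibroblast-like shares were 8.30%, 8.33% and 7.17% (28.7%, 25.7% and 28.6% unthinned), against 1.46%, 0% and 1.06% in the lymphoid-like cells (3.38%, 0% and 2.80% unthinned).

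Both genes were lower in knockout keratinocyte-like cells. Yap1 was 109 CPM [105 to 113] in the young control, 21.3 [15.4 to 28.7] in the knockout and 74.7 [69.6 to 80.2] in the old control. Wwtr1 was 125 [121 to 129], 0.992 [0.120 to 3.58] and 125 [119 to 132]. Cluster 25, led by cell cycle genes, held 56 of the 109 knockout cells of this class and 138 of the 2323 young control cells, and without it the knockout levels were 26.6 CPM for Yap1 and 2.66 CPM for Wwtr1. In vascular endothelial-like cells Wwtr1 was 331 CPM [310 to 354], 11.1 [6.22 to 18.3] and 201 [176 to 229], and Yap1 was 59.9 [50.9 to 69.9], 35.6 [26.2 to 47.2] and 67.9 [53.7 to 84.6]. Of the knockout endothelial-like cells, 257 of 354 lay in a cluster that the other libraries lack. Without it the knockout levels were 19.7 CPM for Wwtr1 and 32.8 CPM for Yap1. Knockout Wwtr1 also stood at 26.1 CPM against 398 in lymphatic endothelial-like cells, 6.45 against 166 in pericyte or smooth muscle-like cells and 9.32 against 145 in dermal papilla or sheath-like cells. Yap1 stood at 32.6 against 90.8, 59.1 against 74.0 and 77.3 against 69.5 CPM in the same classes. Different clusters held most of these cells, except for the lymphatic class, which was cluster 9 in every library. Of the pericyte or smooth muscle-like cells, 475 of 562 knockout cells lay in cluster 22 (Myh11, Cnn1, Actg2) and 323 of 383 young control cells in cluster 24 (Rgs5, Gm13889, Aoc3). Of the 93 knockout dermal papilla or sheath-like cells, 48 lay in cluster 40, which held no cell of the other libraries, and the young control cells all lay in cluster 3.

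**Figure D1:**
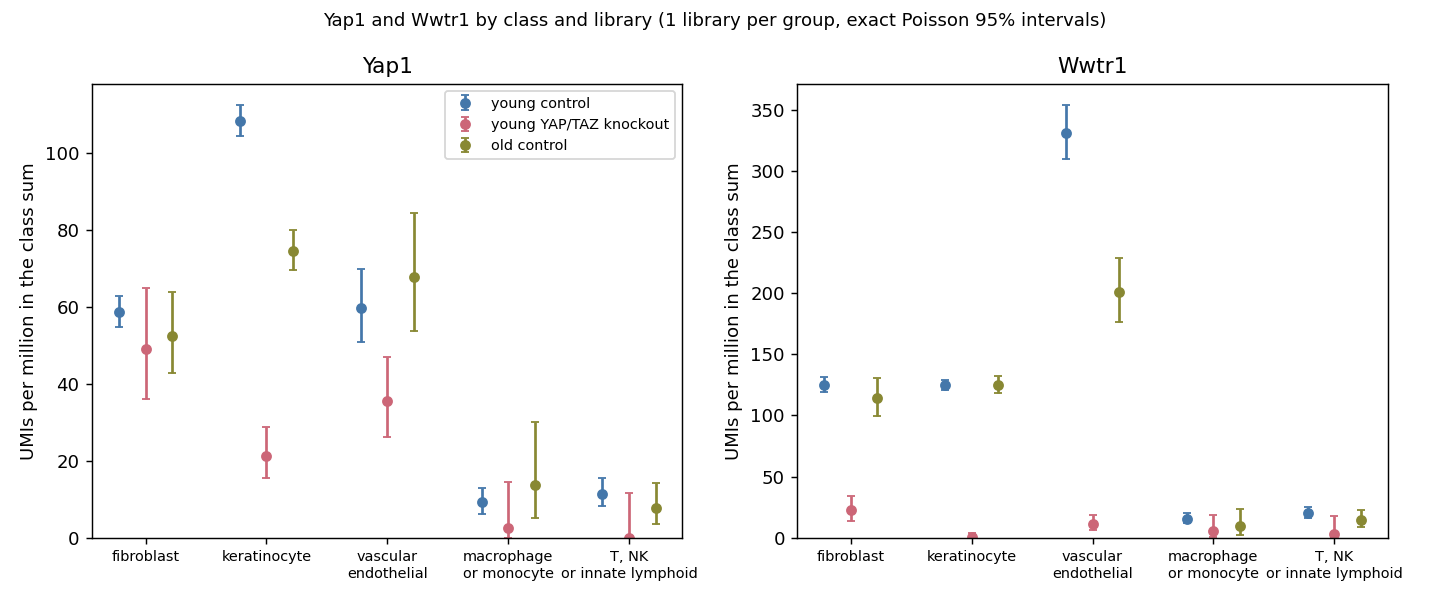
Yap1 (left) and Wwtr1 (right) in CPM of the class sum (y axis), by named class (x axis) and library (colour), with points for the 1 library per group and bars for exact Poisson 95% intervals. Wwtr1 in fibroblast-like cells lies at 125, 22.5 and 114 CPM in the young control, knockout and old control, while the Yap1 intervals of the 3 libraries overlap there.

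Knockout against young control asks what deletion of YAP/TAZ does at equal age and treatment. By the sex-linked genes given below these libraries also differed in sex, so sex and genotype cannot be told apart in their differences. In fibroblast-like cells of the knockout library, protein folding genes of the endoplasmic reticulum and actin cytoskeleton genes were higher, and fascia fibroblast and MHC class I genes were lower. Papillary dermal fibroblast genes were also higher and complement genes lower in the class sum, but of clusters 6, 13 and 21 each of these lists passed the random range in cluster 21 only. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), the main folding chaperone of the endoplasmic reticulum, stood at 1197 CPM against 561.7, a ratio of 2.13 [2.00 to 2.27]. Collagen I was lower: Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had a ratio of 0.426 [0.417 to 0.436] and Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) one of 0.392 [0.384 to 0.399]. The median of canonical YAP/TAZ target genes lay inside the random range. By the size rule 4 of the 19 members were lower and 1 was higher, beside 233 lower and 259 higher of all 6069 genes.

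By the size rule 259 of 6069 genes were higher and 233 lower, which describes these libraries. The median gene lay at a log2 ratio of 0.17. TMM factors shifted all genes by −0.14 on the log2 scale and gave 182 higher and 303 lower. Median-of-ratios factors shifted them by −0.11 and gave 200 and 288, so the balance of the directions depends on the scaling. In thinned cells 204 genes were higher and 147 lower, and after free RNA subtraction 378 and 219.

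The highest ratios included genes with few UMIs in the young control, 7 to 32 in the class sum. Pgr, the progesterone receptor (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611), stood at 114 CPM against 0.492, a ratio of 231 [108 to 587]. Lrrtm3 (98.6-fold), Flrt1 (45.2-fold) and Pthlh, which encodes parathyroid hormone-related peptide (37.3-fold), followed. All 4 came mainly from cluster 6, which held 82 of the 111 Pgr UMIs. Hspa1b, an inducible heat shock chaperone (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), was 11.5-fold higher [10.8 to 12.2], and this held in clusters 6, 13 and 21 (23.6-fold, 10.2-fold and 5.49-fold). Crabp1, a retinoic acid binding protein (11.1-fold), the formin Inf2 (8.72-fold), the lipid desaturase Scd2 (8.03-fold) and Arntl, the clock activator BMAL1 (10.4-fold), were also among the highest. Crabp1 was among the leading genes of clusters 3 and 40, named dermal papilla or sheath. That class held 93 knockout cells, too few for the free RNA rule, which thus could not take Crabp1 as RNA of those cells. The Wnt antagonists Wif1 (ENSMUSG00000020218, chromosome 10, 121033960 to 121100650; 15.2-fold, 12.4 to 18.7) and Sfrp2 (10.3-fold) rested on cluster 21 alone. All 198 knockout UMIs of Wif1 lay there, where its ratio was 5.81, and without that cluster both genes had 0 knockout UMIs. With each library clustered alone, the Wif1 ratio was 0.256.

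Among the lowest ratios were Plac8, with 0 UMIs in the knockout and at least 33.0-fold lower than the young control, and Dbp, a clock output factor (0.0320 [0.0117 to 0.0697]). Mgp, the matrix Gla protein that inhibits calcification, had a ratio of 0.0585 [0.0311 to 0.1002]. The chemokines Cxcl9 (0.05004 [0.0103 to 0.147]) and Ccl8 (0.0929 [0.0606 to 0.136]) were low as well. So were the matrix genes Thbs4 (0.0685), Hmcn2 (0.0761) and Col14a1 (0.113), the transporter Slco2b1 (0.129) and the carboxypeptidase Cpz (0.139). With the young control clustered alone, Plac8, Thbs4 and Hmcn2 were leading genes of a cluster of 286 cells, 284 of them in cluster 13. Cluster 13 held 887 of 2328 young control but 16 of 144 knockout fibroblast-like cells. Part of these 3 ratios may thus go with the mix of clusters. The sex-linked genes Ddx3y (at least 635-fold higher) and Xist (at least 348-fold lower) headed both ends. Ddx3y is Y-linked and Xist is expressed from the inactive X chromosome, so by these genes the knockout library was male and both controls were female. Sex and genotype cannot be told apart in any knockout difference given here.

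Of the 26 lists, 4 lay above and 10 below the random range in this comparison. The protein folding list had a median log2 ratio of 1.09 (percentile 100), with 13 of 15 members higher and 7 past the size rule. Hsp90b1 (2.26-fold), Pdia4 (3.02-fold) and Sdf2l1 (4.55-fold) led with Hspa5. The list stayed called in every setting run and in each of clusters 6, 13 and 21 (medians of 1.16, 0.73 and 0.74). The actin cytoskeleton list lay at 0.63 (100), with 22 of 26 members higher, among them Actb (1.35-fold), while Actg1 stood at 1.04 [0.994 to 1.09] and at 0.941 with TMM factors. This list stayed called in every setting run, and by cluster it lay at 0.59 (99.95), 0.43 (96.7) and 0.51 (100). Tpm1 (3.31-fold) and Tpm2 (3.36-fold) were also higher, and both are abundant enough in other classes to count as free RNA.

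The papillary list lay at 1.42 (100), with 9 of 10 members higher, including Prdm1 (7.78-fold) and Trps1 (1.95-fold), and Ntn1 at 0.985. Its median was 0.88 with the cluster mix of the young control. Within clusters 6, 13 and 21 it was 0.61 (93.8), 0.43 (71.2) and 0.58 (99.6). With each library clustered alone its median was 0.45 (95.2) and the call ended. Of the 73 knockout cells of cluster 21, 59 lay in a mixed cluster there. The fascia and adventitial list lay at −0.86 (0), with 11 of 11 members lower, among them Sema3c (0.269), Opcml (0.336), Pi16 (0.502) and Ly6a (0.631). By cluster it was −0.31 (2.03), −0.40 (5.09) and −0.47 (0.62). With the cluster mix of the young control and without the 16 knockout cells of cluster 13, Opcml was at 1.14.

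MHC class I genes lay at −0.68 (0), with 9 of 10 members lower, including B2m (0.593), H2-K1 (0.538), Tap1 (0.424) and Nlrc5 (0.395). Complement genes lay at −0.83 (0), with 8 of 10 lower, including C3 (0.232) and Serping1 (0.631), and the call ended without cluster 13 at the young control mix (−0.33, 2.87). Within clusters 6, 13 and 21 it lay at −0.036 (24.2), −0.40 (6.40) and −0.71 (0.050). Adipogenic genes lay at −0.47 (0.5), with 9 of 12 lower, among them Apoe (0.363), and Agt at 6.20-fold. After free RNA was subtracted the median was −0.22 (6.59), and by cluster it was −0.24 (4.93), −0.47 (2.71) and −0.60 (0.415).

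Fibrillar collagen genes lay at −0.27 (0.8), with 12 of 19 lower, including Sparc (0.397). The call ended with doublets kept (−0.155, 3.65) and without cluster 13 at the young control mix (−0.031, 15.5), and within cluster 13 the list lay at −0.17 (11.6). Immediate-early and dissociation stress genes lay at −0.26 (1.4), with 11 of 20 lower. Fos (0.858) and Egr1 (0.635) were lower while the heat shock genes Hspa1a (6.81-fold) and Hspa1b were higher, and the call ended in several settings, among them thinned cells (−0.14, 8.80) and doublets kept (−0.15, 7.80). In cluster 21 the list lay at 0.023 (24.4). Senescence-associated secreted factors lay at 0.40 (98.1), with 12 of 19 higher, but Cxcl12 (0.216) and Ccl8 were lower, and the call ended in most settings, with −0.014 (34.2) without cluster 21 and 0.063 (41.5) in thinned cells, and inside the random range in each of clusters 6, 13 and 21 (0.16, −0.25 and 0.15).

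Lists within the random range were YAP/TAZ targets at −0.063 (5.9; 9 of 19 higher), Hippo pathway and TEAD factors at 0.12 (35.5), basement membrane at −0.16 (3.1), elastic fibre and glycoproteins at −0.19 (3.0), myofibroblast genes at 0.33 (83.4) and nuclear lamina at 0.38 (91.3). The cGAS-STING pathway lay at −0.048 (21.6), cell-cycle inhibitors at 0.40 (95.7), cell cycle at −0.0092 (25.2), oxidative phosphorylation at 0.28 (86.8) and endothelial adhesion genes at −0.45 (3.5). Some of these were called in other settings. Elastic fibre genes lay below the random range in each of clusters 6, 13 and 21 (−0.26, 0.86; −0.39, 1.10; −0.35, 0.050), basement membrane genes in clusters 6 and 13 (−0.30 and −0.84) but not 21 (0.029), and endothelial adhesion genes in cluster 6 (−0.61, 1.47). Without cluster 21, elastic fibre genes lay at −0.37 (0.42), basement membrane genes at −0.66 (0.02) and myofibroblast genes at −0.34 (1.38). After free RNA subtraction, nuclear lamina genes lay at 0.64 (99.33), cell-cycle inhibitors at 0.56 (98.33) and endothelial adhesion genes at −0.69 (1.30). Among YAP/TAZ targets, Cyr61 stood at 1.04 [0.986 to 1.09] and at 0.939 with TMM factors, Ccdc80 at 0.634, F3 at 0.259 [0.137 to 0.446] and Igfbp3 at 0.239. Within matrix lists, Fn1 (0.196) and Ogn (0.329) were lower, Tnc was 5.97-fold higher in cluster 21 cells only, and Col6a3 was at 1.16 but at 0.625 without cluster 21. Lmna was 1.43-fold and Emd 2.23-fold, while Lmna was at 0.933 with libraries clustered alone. Cdkn1a stood at 1.32 (0.962 with libraries clustered alone), and Cdkn2a, the p16 and p19 locus, at 3.93 [1.74 to 8.06] on 10 knockout UMIs.

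Interferon-stimulated genes lay at 0.17 (53.6), with 15 of 24 higher. Isg15 was 4.46-fold higher [3.32 to 5.91] and Gbp2 lower (0.210). The clusters differed: the list lay at 0.72 (99.97) in cluster 6 with 22 of 25 members higher, at −0.77 (0) in the 16 knockout cells of cluster 13 and at 0.19 (83.4) in cluster 21. Without cluster 13 at the young control mix the list was called at 0.61 (99.98), without cluster 21 at 0.53 (99.64), with libraries clustered alone at 0.45 (99.63) and with doublets kept at 0.39 (98.47).

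Transcripts of epidermis, blood and antigen-presenting cells were lower, beside a lower free RNA estimate. Basal and stress keratins lay at −2.23 (0), epidermal differentiation genes at −2.56 (0), haemoglobin at −2.84 (0) and MHC class II genes at −2.55 (0). Members included Krt5 (0.242), Krt77 (0 UMIs, at least 50.5-fold lower), Dsg1a (0 UMIs, at least 7.45-fold lower), Hbb-bs (0.151) and Cd74 (0.121). With members at 0 set to their floor the differentiation median stayed at −2.56. Free RNA was estimated at 17.0% of UMIs in young control, 6.2% in knockout and 15.7% in old control fibroblast-like cells, and after subtraction the haemoglobin list was at 3.69. In cluster 21 haemoglobin lay at −0.69 (7.81).

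**Figure D2:**
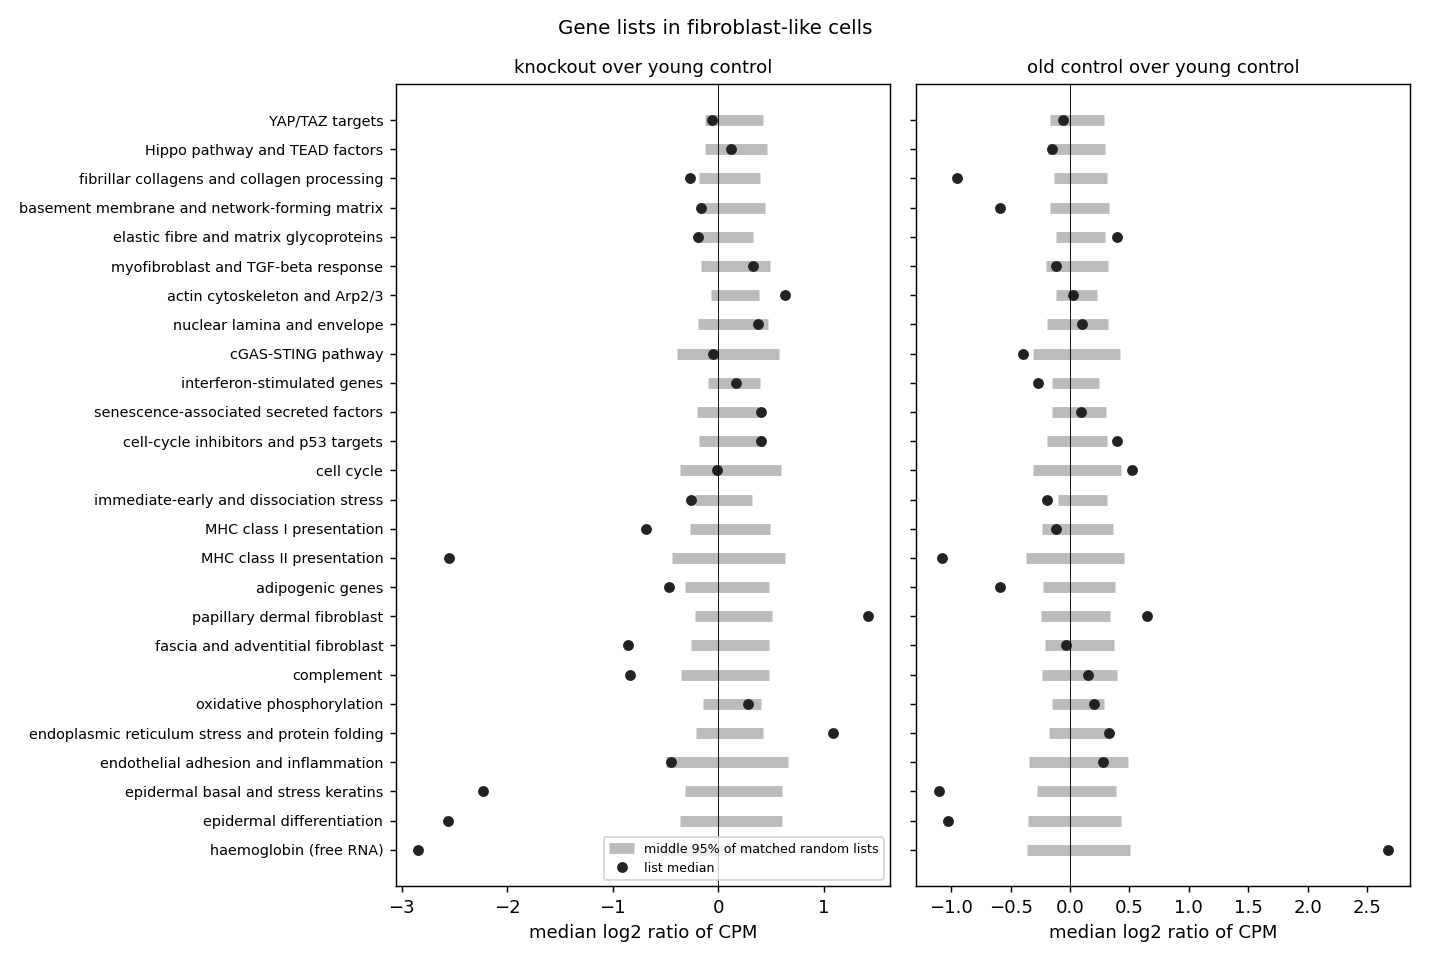
Median log2 ratio of CPM (x axis) of the 26 gene lists (y axis) in fibroblast-like cells, for knockout over young control (left) and old over young control (right, on its own scale). Points are list medians and grey bars the middle 95% of 10000 matched random lists. Protein folding lies at 1.09 in the knockout, fibrillar collagens at −0.95 in the old control.

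Old against young control describes skin at 24 months, with genotype and tamoxifen differing as well, so age cannot be separated from them. In fibroblast-like cells of the old control, fibrillar collagen and basement membrane genes were lower, in each of clusters 6, 13 and 21, and the proteoglycan genes Dcn and Lum were higher in the class sum. Col1a1 stood at 5181 CPM against 19730 in the young control, a ratio of 0.263 [0.257 to 0.268]. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) had a ratio of 0.231 [0.225 to 0.237] and Col1a2 one of 0.317 [0.312 to 0.322]. The proteoglycans decorin (Dcn, 1.47-fold) and lumican (Lum, 1.38-fold) were higher, but stood at 0.952 and 0.879 with the mixed cluster 4 included. By the size rule 106 of 6069 genes were higher and 140 lower. With cluster 4 included 248 were higher and 189 lower, in thinned cells 76 and 71, and with TMM factors 85 and 162.

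The highest ratios were those of Gpm6a, a neuronal membrane glycoprotein (ENSMUSG00000031517, chromosome 8, 54954843 to 55060871; 24.1-fold, 17.0 to 35.0), and Rxfp1, the relaxin receptor (ENSMUSG00000034009, chromosome 3, 79641611 to 79737880; 10.5-fold, 8.35 to 13.2). Both were higher in each of clusters 6, 13 and 21. Grem1, a BMP antagonist (4.91-fold), the oxytocin receptor Oxtr (4.98-fold), fibromodulin (Fmod, 4.03-fold) and the cytokine signalling inhibitor Socs2 (4.39-fold) followed. Akr1c14 (4.34-fold), C1qtnf7 (4.08-fold), Inhbb (4.06-fold), Cyp2f2 (3.67-fold), Cck (4.14-fold) and Negr1 (4.02-fold) completed the highest 12. Fmod (0.342) and Cck (0.434) were below 1 when libraries were clustered alone, and Cck had 0 old control UMIs without cluster 21.

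The lowest ratios included Gbp2b and the chemokine gene Cxcl9. Gbp2b, an interferon-induced GTPase, had 0 UMIs in the old control and was at least 53.6-fold lower. Cxcl9 (0.0255 [0.00524 to 0.0747]), Plac8 (0.0566) and the pentraxin Ptx3 (0.0635) were low, and so were Ifi27l2a (0.190), the antioxidant enzyme Gpx3 (0.219), the apolipoprotein Apoe (0.254), tissue factor (F3, 0.162), Col4a4 (0.155) and the angiotensin-converting enzyme Ace (0.186). Gpx3 led cluster 13, which held 887 of 2328 young control but 41 of 294 old control cells. Part of its ratio may thus go with the mix of clusters.

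Of the 26 lists, 6 lay above and 9 below the random range. Fibrillar collagens lay at −0.95 (0), with 17 of 19 members lower and 9 past the size rule, Col5a3 (0.228) among them. Basement membrane genes lay at −0.59 (0), with 12 of 15 lower, including Col6a3 (0.393), Col6a1 (0.571) and Col4a1 (0.437), and adipogenic genes at −0.59 (0), with 11 of 12 lower, Cebpb (0.816) and Agt (0 UMIs, at least 2.43-fold lower) among them. The adipogenic median was the same with Agt at its floor. These 3 lists stayed called in every setting run. Within clusters 6, 13 and 21 adipogenic genes lay at −0.66 (0.02), −0.58 (0.35) and 0.025 (40.1), with 6 of 11 members higher in cluster 21.

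Elastic fibre and glycoprotein genes lay at 0.39 (99.8), with 15 of 20 higher, although elastin itself was lower (Eln, 0.331). In thinned cells it was at 0.29 (96.1), and it turned to −0.22 (5.77) with the mixed cluster 4 included. Papillary genes lay at 0.65 (100), with 9 of 10 higher, such as Col23a1 (2.67-fold), Apcdd1 (2.20-fold), Ntn1 (1.55-fold) and Trps1 (1.44-fold). With cluster 4 included the list was at 0.32 (95.4), and Trps1 was at 0.8625 without cluster 13 at the young control mix. Cell-cycle inhibitors and p53 targets lay at 0.40 (99.7), with 12 of 17 higher. Cdkn2a was 5.20-fold higher [3.02 to 8.82], Gdf15 2.63-fold and Cdkn1a 1.42-fold, and the list was at 0.30 (88.5) in thinned cells and 0.32 (94.2) after free RNA subtraction. Cell cycle genes lay at 0.53 (99.3) on 8 members, with Ccnd1 (2.05-fold) and Hmgb2 (2.15-fold), and at 0.43 (89.98) in thinned cells. Protein folding genes lay at 0.33 (98.2), with Hsp90b1 (1.56-fold), Pdia6 (1.90-fold) and Sdf2l1 (3.32-fold) higher and Hspa5 at 1.06 [0.990 to 1.12], and at 0.27 (91.4) in thinned cells and 0.042 (62.4) with cluster 4 included. Within clusters 6, 13 and 21, cell-cycle inhibitors (0.27, 0.29 and 0.36) and cell cycle genes (0.39, 0.31 and 0.30) lay inside the random range. Papillary genes passed it in cluster 13 only (0.39, 0.94 and 0.21), protein folding genes in cluster 6 only (0.41, 0.31 and 0.12) and elastic fibre genes in clusters 6 and 13 (0.40, 0.50 and 0.075).

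Interferon-stimulated genes lay at −0.27 (0.1), with 16 of 24 lower, among them Cxcl10 (0.262), while Ifitm3 was 1.47-fold and Ifi27 1.28-fold higher. In thinned cells the list was at −0.12 (5.18), and by cluster at −0.0070 (24.4), −0.16 (7.41) and −0.34 (0.13). The cGAS-STING pathway lay at −0.40 (1.0), with 7 of 8 lower, such as Samhd1 (0.686), and at −0.36 (3.15) in thinned cells and −0.30 (4.65) with cluster 4 included, and passed the random range in cluster 21 only (−0.43, 1.66). Immediate-early genes lay at −0.19 (0.3), with Egr1 (0.774) and Dusp1 (0.662) lower and Ier3 1.98-fold higher, at 0.011 with cluster 4 included, and past the random range in cluster 6 only (−0.33). MHC class II genes lay at −1.08 (0), basal keratins at −1.11 (0) and differentiation genes at −1.03 (0), and all 3 turned to positive values with cluster 4 included (2.50, 2.11 and 0.97). Haemoglobin lay at 2.68 (100), with Hbb-bs 7.49-fold higher, and at −4.21 with libraries clustered alone. The higher value was that of cluster 6 (3.39), while clusters 13 and 21 lay at −4.84 (0) and −2.69 (0). MHC class II genes lay at −1.15 (0), 0.14 (61.9) and −1.97 (0) in the 3 clusters.

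Lists within the random range were YAP/TAZ targets at −0.063 (14.3; 7 of 19 higher), Hippo pathway at −0.16 (4.4), myofibroblast genes at −0.12 (10.6), actin cytoskeleton at 0.021 (34.4), nuclear lamina at 0.10 (64.3) and secreted factors at 0.095 (52.2). MHC class I lay at −0.12 (10.1), fascia genes at −0.032 (22.3), complement at 0.15 (68.2), oxidative phosphorylation at 0.20 (90.6) and endothelial adhesion genes at 0.28 (84.0). Among YAP/TAZ targets Cyr61 (0.650) and Igfbp3 (0.131) were lower. The YAP/TAZ target list was called at −0.29 (0.17) without cluster 21, at −0.20 (1.85) at the young control mix, at −0.17 (1.93) as a mean over cells and at −0.30 (0.87) with cluster 4 included. Myofibroblast genes were called at −0.58 (0) at the young control mix, and lay below the random range in each of clusters 6, 13 and 21 (−0.41, −0.47 and −0.52). Other lists passed that range in single clusters. In cluster 6 complement (0.70, 99.82), fascia (0.60, 99.79) and secreted factors (0.37, 97.65) lay above it. In cluster 21 YAP/TAZ targets (−0.26, 0.62) and MHC class I genes (−0.41, 0.39) lay below it, and Hippo pathway genes did in clusters 13 (−0.35, 1.12) and 21 (−0.33, 0.33). With cluster 4 included, complement (−0.57, 0.16), fascia (−0.45, 0.90), secreted factors (−0.42, 0.12) and Hippo pathway genes (−0.33, 0.62) were below the random range. Syne1 was 2.01-fold, Igfbp7 1.92-fold and Lrrc15 2.78-fold higher, the last at 0.668 without cluster 21. Cxcl12 (0.337) and Vcam1 (0.308) were lower, and Cxcl12 was at 1.13 without cluster 13 at the young control mix.

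Knockout and old control differences pointed the same way more often than counting error gives. Of the genes past the size rule, 31 were higher in both (4.5 for independent lists) and 68 were lower in both (5.4), while 6 (6.0) and 8 (4.1) went opposite ways. Cxcl9, Plac8, Apoe, F3, Col1a1 and Col1a2 were among those lower in both. Genes taken as free RNA were not left out of these counts. Basal keratin, epidermal differentiation and MHC class II lists had 5, 6 and 4 members past the lower rule in the knockout. In the old control they had 4, 3 and 3. Across 6069 genes, which are not independent replicates, the covariance of the log2 ratios was 0.155, against 0.00318 simulated for unchanged libraries, and the correlation was 0.390 against 0.0865. With the control's cells split between the comparisons they were 0.147 and 0.371. At the young control mix of clusters they were 0.113 and 0.273. Cluster 13 held 887 of 2328 young control, 16 of 144 knockout and 41 of 294 old control cells. The overlap of genes past the size rule was not computed at that mix. Both comparisons share 1 control library, which cannot be split into libraries, so part of the excess may come from that control or from the mix of clusters.

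Keratinocyte-like cells numbered 2323 in the young control, 109 in the knockout and 1360 in the old control, and different clusters held most of them. Cluster 25, led by the cell cycle genes Cenpf, Ube2c and Mki67, held 138, 56 and 232 cells in that order, and cluster 14 (Krt10, Krtdap, Mt4) 556, 34 and 261. Cluster 11 (Fcgbp, Serpinb2, Clca2) held 901, 3 and 183, cluster 16 (Pyy, Fst, Ccl27a) 567, 5 and 224, and cluster 20 (Sprr1a, Cst6) 161, 11 and 460. The median cell held 8199, 3309 and 3453 UMIs, with a mitochondrial share of 4.62%, 9.05% and 5.40%. In clusters 14 and 25 that share was 11.03% and 9.10% in the knockout against 4.54% and 4.35% in the young control. Knockout values rest mainly on clusters 14 and 25, so the value within each of these, in that order, is given after the class value.

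In the knockout library, interferon-stimulated and MHC class I genes were lower and protein folding and oxidative phosphorylation genes higher, in the class and in both clusters. Interferon-stimulated genes lay at −1.07 (0), with 17 of 17 lower, such as Cxcl10 (0.136), and at −1.14 (0.01) and −1.0 (0.01) in clusters 14 and 25. MHC class I genes lay at −0.89 (0), with 10 of 10 lower, and at −0.65 (0.33) and −1.09 (0). Protein folding lay at 0.53 (99.95), 0.60 (99.93) and 0.33 (99.92), and oxidative phosphorylation at 0.55 (99.99), 0.37 (99.5) and 0.34 (99.86). Basement membrane genes lay at 0.76 (99.99), 1.69 (100) and 0.11 (98.7), but at −0.012 (75.0) without cluster 25. YAP/TAZ targets lay at −0.38 (6.45), within the random range. In cells with 4 to 8% mitochondrial UMIs, 36 knockout cells with a median of 25467 UMIs and 1368 young control cells with 8205, interferon-stimulated genes lay at −1.09 (0), MHC class I at −0.92 (0), protein folding at 0.40 (99.51) and oxidative phosphorylation at 0.57 (99.97). There basement membrane genes lay at −0.58 (10.0) and YAP/TAZ targets, below the random range, at −0.63 (0.65). The stress keratin Krt6a was 5.64-fold higher (5.68-fold and 6.19-fold in clusters 14 and 25), and Krt17 stood at 3.25-fold but at 0.611 [0.303 to 1.10] in cluster 14. Cell cycle genes lead cluster 25, so their class median of 1.54 is not read as a difference. Without that cluster they lay at 0.18 (92.6), and within it at −0.34 (1.85).

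In the old control, interferon-stimulated genes of keratinocyte-like cells lay at −0.71 (0), with 17 of 17 lower. They lay below the random range in clusters 11, 14, 16 and 25 (−1.03, −0.77, −1.36 and −0.81), but not in cluster 20 (−0.061, 33.0), which held the most old control cells. Cell cycle genes outside cluster 25 lay at 0.35 (100), with 10 of 12 measured members higher.

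In vascular endothelial-like cells, values for the knockout are given without cluster 35, the 257 cells found there alone. The remaining cells lay in cluster 17 (Fabp4, Cd93, Cd36; 572 young control, 79 knockout and 144 old control cells) and cluster 31 (Selp, Sele, Fabp4; 66, 18 and 237), so cluster 31 held most of the old control cells. The median mitochondrial share of these cells was 5.31% in the young control, 9.72% in the knockout and 6.66% in the old control. Acta2 was 22.7-fold higher in the knockout with cluster 35 and 1.64-fold [1.29 to 2.07] without it. In the remaining 97 knockout cells, protein folding genes lay at 0.54 (100), with 11 of 15 higher, and at 0.56 (99.98) and 0.19 (75.7) in clusters 17 and 31. MHC class I genes lay at −0.51 (0.35), −0.48 (0.52) and −0.72 (0.40). Interferon-stimulated genes lay at 0.040 (88.1), although Isg15 was 4.63-fold higher [3.80 to 5.62], and YAP/TAZ targets at −0.39 (5.10). In the 28 knockout and 333 young control cells with 4 to 8% mitochondrial UMIs, with medians of 7373 and 3430 UMIs, protein folding lay at 0.74 (100) and MHC class I at −0.39 (1.02). Lists of other cell types were low in the 97 cells, with basal keratins at −1.83 (0), epidermal differentiation at −2.38 (0) and haemoglobin at −5.84 (0).

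In the old control, interferon-stimulated genes of vascular endothelial-like cells lay at −0.87 (0), with 23 of 26 lower, at −0.81 (0.01) in cluster 31 and, inside the random range, at −0.18 (31.8) in cluster 17. MHC class I genes lay at −0.68 (0.48), and at −0.41 (6.84) and −0.63 (1.65) in clusters 17 and 31. Elastic fibre genes lay at 0.82 (100), but inside the random range in both clusters (0.13, 80.1, and 0.30, 97.0). Other lists of fibroblast or epidermal transcripts moved with them, with papillary genes at 0.95 (99.99), basal keratins at 0.60 (99.64) and epidermal differentiation genes at 0.60 (99.67), while haemoglobin lay at −5.17 (0).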

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

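The dilution test with the elastic fibre list, the values of single clusters and the tests at the young control mix of clusters, with and without cluster 13, were chosen after the result was seen. The library of the knockout held 5647 UMIs of the Y-linked Ddx3y against 0 in the young control and 1 in the old control, a signal outside the comparisons of cell classes. The other Y-linked genes went the same way (Eif2s3y 2349, 0 and 0 UMIs; Uty 803, 11 and 1; Kdm5d 478, 7 and 3), while Xist had 14 UMIs in the knockout against 166112 and 76236. The 3 patterns weighed here are the papillary and fascia lists in the knockout, the collagen list in the old control and the protein folding list in the knockout.

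In the knockout library papillary genes were higher and fascia genes lower. The values argue against a different mix of clusters 6, 13 and 21 as the whole cause. At the young control mix the medians stayed outside the random range at 0.88 and −0.51, and without the thinly filled cluster 13 at 1.0 and −0.34. But the papillary median had been 1.42, and single clusters passed that range for papillary genes in cluster 21 only and for fascia genes in clusters 6 and 21. Weighting by cluster cannot test a different mix of cells inside a cluster, which stays open. The values also argue against free RNA, since both lists stayed outside that range after its subtraction (1.43 and −1.07). The papillary call ended when each library was clustered alone (0.45), so it depends on which cells are counted as fibroblast-like. Only 1 library had more Ddx3y than Xist UMIs, and it was the knockout library, so sex and loss of YAP/TAZ cannot be told apart for these lists.

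In the old control library fibrillar collagen genes were lower. The main median was −0.95. The mix of clusters did not account for all of this, as the list stayed below the random range at the young control mix (−0.67) and without cluster 13 (−1.11). Depth did not account for all of it either, with −0.59 in thinned cells. The median cell held 5862 UMIs in the young control and 6454 in the old control, so thinning had little difference in median depth to remove. It also gave every cell equal weight, and the smaller value there is not read as a share due to depth. A part may go with the mix. Dilution by RNA of other cells would lower abundant fibroblast genes alike, while the elastic fibre list lay at 0.39. That list lay inside the random range in thinned cells (0.29, percentile 96.1) and in cluster 21 (0.075), and turned to −0.22 with the mixed cluster 4 included, so this argument holds for the summed class and for clusters 6 and 13, where the elastic fibre list lay at 0.40 and 0.50 and the collagen list at −0.99 and −0.70. Age, genotype and tamoxifen remain open together, and lower collagen expression with age is a hypothesis that this design does not isolate.

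In the knockout library protein folding genes were higher. The list stayed above the random range at the young control mix (1.003) and without cluster 13 (1.04). Damaged cells were weighed in cells with 4 to 8% mitochondrial UMIs (1280 young control and 90 knockout cells), where the median was 1.07. The knockout was the only library, 1 of 3, with more Ddx3y than Xist UMIs, so sex cannot be told apart from genotype here either. Handling of the sample, with the time of day of its collection, remains untested, and a response to loss of YAP/TAZ stays a hypothesis.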

How the results depend on the processing

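The alternatives with the mixed cluster 4 included, at the young control mix of clusters with and without cluster 13, and without cluster 21 were chosen after the data were seen, as were keratinocyte-like cells without cluster 25, endothelial-like cells without cluster 35 and both classes at 4 to 8% mitochondrial UMIs. No paired analysis was possible because each group had 1 library and no result comes from a test. Where no reason is given, the cause was not tested. Kept within counting error were 231 of 231 single-gene ratios with the looser filter, 229 with the stricter one, 187 with median-of-ratios factors, 174 with TMM, 199 with the mean over cells, 185 with doublets kept, 145 in thinned cells, 142 with libraries clustered alone, 137 with cluster 4 included, 125 at the young control mix and 117 without cluster 21. Without cluster 13 at that mix 108 of 230 were kept, as Pgr had no value. Free RNA subtraction kept 157 of 201 ratios and left none for 30, most of them of epidermal, MHC class II or haemoglobin genes, and none for 6 lists. The correlation and the covariance were not computed after that subtraction, in thinned cells or for the mean over cells. They were not computed with TMM or median-of-ratios factors either. TMM and median-of-ratios factors move all genes of a comparison alike, so they do not test list percentiles. The looser filter hardly tests gene values, since most cells it adds lie outside the class. Of 50 list medians, those of YAP/TAZ targets not counted, 50 held with the looser and 49 with the stricter filter, 41 with doublets kept, 40 with the mean over cells, 34 in thinned cells, 31 with libraries clustered alone, 28 at the young control mix (29 without cluster 13), 26 with cluster 4 included and 22 without cluster 21, and 30 of 44 after free RNA subtraction. Depth limits low genes, as a single UMI in the thinned knockout class decides Wwtr1. Ratios below are over the young control, list values are median log2 ratios, and all but the last paragraph concern fibroblast-like cells.

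Shares in the young control, knockout and old control were 17.1%, 0.920% and 1.48% with the looser filter and 25.2%, 4.54% and 6.51% with the stricter one. With libraries clustered alone they were 22.9% and 0.990% in the young control and knockout, and with cluster 4 included 23.7% and 13.0% in the young and old control.

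With libraries clustered alone, old control haemoglobin lay at −4.21 (Hbb-bs 0.0631, Hbb-bt 0.0411, Hba-a1 0.0525), the correlation of both comparisons was 0.364, and Fmod (0.342) and Cck (0.434) turned. In the knockout Col6a3 (0.596), Lmna (0.933), Lama2 (0.992), Lmnb2 (0.560), Wif1 (0.256) and Cdkn1a (0.962) turned lower, Tnc had a ratio of 0 and Tgfbi was at 1.17. TMM put old control Fos at 0.990. Free RNA subtraction put the knockout haemoglobin list at 3.69 and old control Actb at 0.996.

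In thinned cells knockout Wwtr1 was 0.0366, and 147 knockout and 71 old control genes were lower by the size rule, since fewer counts widen intervals. Knockout Amot was 0.779, Tead3 0.940 and Cdkn2b had a ratio of 0, and old control Nlrc5 was 1.24. With genes of at least 10 counts, more genes entered: 436 were higher and 446 lower in the knockout, 268 and 329 in the old control, and the covariance was 0.364.

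With cluster 4 included, the old control lists were YAP/TAZ targets −0.30, elastic fibre −0.22, immediate-early 0.011, MHC class II 2.50, basal keratins 2.11 and epidermal differentiation 0.97. In the old control 248 genes were higher, and the correlation was 0.292. Turned higher were Krt14 (5.18), Krt5 (4.34), Krt15 (3.75), Krt10 (1.81), Krt1 (1.84), Krt77 (1.43), Trp63 (2.50), Lgals7 (4.38), Cd74 (10.2), H2-Aa (6.42), H2-Ab1 (5.66), H2-DMa (4.16), Limch1 (2.45), Lmna (1.16) and Nlrc5 (1.12). Turned lower were Dcn (0.952), Lum (0.879), Igfbp5 (0.884), Serping1 (0.818), Fos (0.923), Ly6a (0.734) and Pi16 (0.763).

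At the young control mix the knockout ratios were 0.558 for Yap1 and 0.110 for Wwtr1, and the knockout lists were 0.28 for YAP/TAZ targets and −0.070 for secreted factors. The covariance was 0.113 and the correlation 0.273, and knockout Col6a3 (0.877), Igfbp7 (0.953) and Cdkn1a (0.990) turned. Without cluster 13 at that mix the covariance was 0.133 and the correlation 0.331. Knockout Igfbp7 (0.998), Opcml (1.14) and Tgfbi (1.06) and old control Postn (1.06), Cxcl12 (1.13), Klf2 (0.988), Opcml (2.08), Fos (0.975) and Trps1 (0.8625) turned.

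Without cluster 21, YAP/TAZ targets were at 0.15 in the knockout and −0.29 in the old control, and knockout secreted factors at −0.014. The covariance was 0.134 and the correlation 0.295. Knockout Wif1, Sfrp2 and Tnc had a ratio of 0, because all their knockout UMIs lay in that cluster, Col6a3 was 0.625 and Tgfbi 1.13. Old control B2m was 1.01, Cck 0, Fos 0.990 and Lrrc15 0.668.

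In keratinocyte-like cells without cluster 25, the knockout lists of basement membrane genes (−0.012) and cell-cycle inhibitors (−0.063) turned. In vascular endothelial-like cells without cluster 35, the knockout lists turned for cell-cycle inhibitors (−0.030), cell cycle (−0.0040), papillary genes (−0.61), oxidative phosphorylation (−0.070) and epidermal differentiation (−2.38), because those cells all belong to the knockout library. At 4 to 8% mitochondrial UMIs, knockout basement membrane genes (−0.58) and cell-cycle inhibitors (−0.017) turned in keratinocyte-like cells. At that range and without cluster 35, knockout cell cycle (−0.175), oxidative phosphorylation (−0.072) and epidermal differentiation genes (−3.53) and old control secreted factors (−0.051) turned in endothelial-like cells.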

Other observations

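The clock genes and the values by cluster, without clusters 25 and 35 or at 4 to 8% mitochondrial UMIs were chosen after the data were seen, and no explanation was tested for any value here.

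Of the 12 circadian clock genes, the output gene Dbp and the repressor gene Nr1d1 were lower in the knockout than in the young control in each of the 6 classes computed. Ratios of Dbp were 0.0320 in fibroblast-like, 0.0535 in keratinocyte-like, 0.229 in lymphatic endothelial-like and 0.295 in T, NK or innate lymphoid-like cells. It was 0.0773 in vascular endothelial-like cells without cluster 35, and macrophage or monocyte-like cells held 0 knockout UMIs (ratio up to 0.303). Ratios of Nr1d1 were 0.367 in fibroblast-like, 0.286 in keratinocyte-like, 0.327 in lymphatic endothelial-like, 0.260 [0.0942 to 0.574] in macrophage or monocyte-like and 0.265 in vascular endothelial-like cells without cluster 35, with 0 knockout UMIs in T, NK or innate lymphoid-like cells (ratio up to 0.246). Arntl, the activator BMAL1, stood at 10.4-fold [7.21 to 14.9] in fibroblast-like cells and at 4.79-fold [1.75 to 12.7] on 9 knockout UMIs in vascular endothelial-like cells without cluster 35. In keratinocyte-like cells it stood at 1.83-fold [1.34 to 2.46], and at 1.71-fold [0.985 to 2.79] without cluster 25. No difference of Arntl was detectable at this depth in T, NK or innate lymphoid-like (0.635 [0.269 to 1.28]), macrophage or monocyte-like (1.13 [0.290 to 3.19]) and lymphatic endothelial-like cells (2.69 [0.757 to 7.89]). The repressor genes Per2 (0.116 [0.0238 to 0.341] on 3 knockout UMIs) and Per3 (0.172) were lower in fibroblast-like cells, as was Tef (0.326), while Cry1 (4.13-fold) and Clock (2.66-fold) were higher there. Cry1 (0.503 [0.277 to 0.866]) and Clock (0.771 [0.596 to 0.991]) were lower in vascular endothelial-like cells with cluster 35. Cry1 was also lower in T, NK or innate lymphoid-like cells (0.231 [0.0276 to 0.856] on 2 knockout UMIs). In keratinocyte-like cells Per3 (0.138) and Tef (0.129) were lower, with Clock at 0.909 [0.727 to 1.12], and Per3 stood at 1.66 [0.918 to 2.82] in T, NK or innate lymphoid-like cells. In the old control Nr1d1 stood at 1.30-fold [1.19 to 1.41] in fibroblast-like cells but at 0.647 [0.604 to 0.694] in keratinocyte-like, 0.655 [0.533 to 0.800] in vascular endothelial-like and 0.664 [0.520 to 0.840] in lymphatic endothelial-like cells. Dbp was 1.60-fold [1.46 to 1.75] in fibroblast-like and 1.05-fold [0.976 to 1.12] in keratinocyte-like cells. Per1 was lower in fibroblast-like (0.600 [0.509 to 0.702]), keratinocyte-like (0.637) and vascular endothelial-like cells (0.515), and Arntl stood at 0.481 [0.152 to 1.17] in fibroblast-like cells. The labels used here give no time of day for tissue collection.

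In keratinocyte-like cells of the knockout library, immediate-early genes lay at −0.82 (percentile 0), with 16 of 20 members lower, among them Fosb (0.416) and Egr1 (0.427), and at −0.64 (0) and −0.32 (0.07) in clusters 14 and 25. Fascia genes, a list of fibroblast transcripts, lay at −1.28 (0), −1.11 (0.09) and −0.92 (0.14), beside haemoglobin at −5.24 (0) in the class. Elastic fibre genes lay at −1.14 (0) and −1.20 (0.01) in the class and cluster 25, but at 0.14 (74.5) in cluster 14. At 4 to 8% mitochondrial UMIs immediate-early genes lay at −0.87 (0), fascia genes at −1.28 (0.04) and elastic fibre genes at −1.70 (0). The chemokine gene Cxcl2 was 13.7-fold higher, with 142 of its 180 knockout UMIs in the 11 cells of cluster 20, and Cxcl1 was 4.53-fold higher. In the old control, fibrillar collagens, also fibroblast transcripts, lay at −0.76 (0), with 12 of 13 lower, and inside the random range in clusters 20 and 25 (−0.20 and −0.35). Other lists of transcripts from elsewhere were low beside it, with haemoglobin at −2.80 (0; 4 of 4 lower), fascia genes at −0.47 (0.59) and MHC class II genes at −0.50 (0.39). Actin cytoskeleton genes lay at 0.19 (99.95), and inside that range in clusters 16 and 25 (−0.098 and −0.036).

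In vascular endothelial-like cells of the old control, senescence-associated secreted factors lay at 0.58 (99.98) and complement genes at 0.61 (99.53). Both lay inside the random range within clusters 17 (−0.13 and −0.014) and 31 (−0.27 and −0.069), and at 4 to 8% mitochondrial UMIs (−0.051 and 0.30). In the knockout without cluster 35, complement genes lay at −1.12 (0.06), and at −1.07 (0.16) and −0.86 (0.61) in clusters 17 and 31. Endothelial adhesion genes lay at 0.42 (99.14), 0.28 (94.4) and −0.45 (2.19), and myofibroblast genes at 0.43 (99.77), 0.40 (99.08) and 0.27 (76.0). At 4 to 8% mitochondrial UMIs the adhesion list turned to −0.28 (1.71), while complement lay at −1.23 (0.09) and myofibroblast genes at 0.57 (99.8). Fibrillar collagens lay at −0.57 (0.445) in the knockout and −0.43 (1.15) in the old control, beside elastic fibre genes at −0.43 (1.69) and 0.82 (100). In cluster 31 the collagen list was inside the random range in both comparisons (0.077 and 0.27), as it was in the old control at 4 to 8% mitochondrial UMIs (−0.28, 7.995).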
